A study of Jaculus jaculus with 29 samples.

How the data were processed

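RNA-seq counts of 29 libraries of jerboa supraoptic nucleus punches were analysed from the deposited tables. Per the labels, animals were housed singly at 25 °C with 12 hours of light, and 12 bilateral punches were taken with a 1 mm core from 100 µm frozen sections. Per the labels, the RNA was polyadenylated, and animals were assigned at random to free water, 11 days of restriction, or 7 days of restriction and 3 days of water. Each library was treated as a separate animal, since the labels number the samples within each group and speak of individually housed animals.

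Per the file header, the deposited counts are whole fragment counts per gene, made by the authors with featureCounts 1.6.2 in paired-end mode on the Ensembl annotation of the mJacJac1 assembly with no strand option given. Reads of a gene and of an antisense or overlapping neighbour can therefore not be told apart, and counts of close copies, such as ribosomal protein genes and their pseudogenes, are uncertain. FastQC, featureCounts and DESeq2 are named in the submitters' processing notes; the aligner is not given in the sources used here. The authors' deposited tables for Dehydrated against Control and Rehydrated against Control hold log2 fold changes with standard errors, p-values and adjusted p-values made with DESeq2, per the submitters' processing notes, for 17583 genes. The mean normalized signal per gene in the authors' deposited tables was not used here. The authors' model is not given in the sources used here: DESeq2 on the deposited counts with group and sex, Control M01 left out, differed from their log2 fold changes by at most 1.6e-06 and 2e-07 in the 2 tables, and with all libraries by up to 3.78 and 3.58. Their tables also hold 56 columns of values per library, 28 in each table, which were not used here. The table for Dehydrated against Control has no column under the code of Control M01.

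The count table holds 29170 genes. The authors' tables name 9699 of them, and another 5594 were named from a RefSeq gene table of the same assembly by an overlap of at least 0.5 of both genes' spans, each the other's best match; 13877 had no name. Where both sources gave a name, it was the same for 96.57% of 8787 genes. Among tested genes 75 had a symbol that more than 1 gene carries, and such genes were treated as uncertain.

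Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr on the group, which left 17558 genes and took out 11612 that hold 0.126% of the counts. Libraries were scaled by TMM, and a robust quasi-likelihood model with group and sex over all 29 libraries (25 residual degrees of freedom) gave each contrast, with Benjamini-Hochberg adjustment and a threshold of 0.05. Sex differences in a response were tested in a model of 6 cells of group by sex. CPM values used the TMM-scaled totals, and the standard error of a log2 fold change was its size divided by the square root of the F statistic. Gene lists with at least 5 tested members, 32 of 34, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Mean log2 CPM of the immediate-early list was compared within the letter of the library name by exact permutation tests. These listed every permutation in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

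Sample groups, sex and replicate names come from the labels; 3 libraries (Control F03, Control M05 and Dehydrated M02) carry a sex label other than the letter in their name, and the label was used. Counts of replicates differed by more than sampling noise in all 126 pairs within groups (chi-square per degree of freedom 8.90 to 162), so none was counted as a duplicate. Pairs with Control M01 ran from 92.8 to 162, and the other pairs reached at most 77.2. The median standard error of a log2 fold change was 0.12 in Dehydrated against Control and 0.13 in the other treatment comparisons. It holds both counting noise and the spread between libraries, which were not measured apart.

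The comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule names 14 transcripts of the vasopressin system in each comparison, the 8 largest rises and falls past the threshold with a mean of at least 1 log2 CPM, the 5 smallest p, and up to 4 members of each list that passed or is discussed. Alternatives were DESeq2 1.42.0, other size factors, filters, covariates and thresholds, a block by replicate number, 2 surrogate variables from sva 3.50.0, the sexes alone, and each library left out in turn. Alternatives chosen after seeing the data left out Control M01 with a further library or under DESeq2, took the name letter as covariate, or removed 108 unnamed genes on 2 repeat-rich contigs.

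The pipeline was tested on simulated data for the 17558 genes, 200 of them changed, drawn from genes with a mean of at least 1 log2 CPM. Counts were drawn independently for each gene and library. The recovery therefore does not cover genes below that level, genes that vary together or a library set apart. In Dehydrated against Control it recovered 173, with 46 of 67 at 1.5-fold, 61 of 67 at 2-fold and 66 of 66 at 4-fold, and 8 false calls (4.42% of calls); DESeq2 recovered 178 with 23 false calls (11.4%). It recovered 174 in Rehydrated against Control, 163 in Rehydrated against Dehydrated, 180 for sex, and 99 and 103 for the sex difference in the dehydration and rehydration effect.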

Results

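The lesser Egyptian jerboa is a desert rodent, and the supraoptic nucleus is the hypothalamic nucleus whose magnocellular neurons release vasopressin and oxytocin. Polyadenylated RNA was sequenced from punches of this nucleus in 29 libraries. Control animals (10 libraries) had free water, Dehydrated animals (10 libraries) had 11 days of water restriction, and Rehydrated animals (9 libraries) had 7 days of restriction and then 3 days of water. Both sexes were in each group, with 5 females and 5 males in Control, 6 and 4 in Dehydrated, and 4 and 5 in Rehydrated. Total counts per library ranged from 10797577 in Control M01 to 18856620 in Dehydrated F04, with group means of 14431600, 16522600 and 16385400 in Control, Dehydrated and Rehydrated. At this depth 17558 genes were tested in 1 model over all libraries, with sex as covariate. Control M01 also had the fewest detected genes, 19384, and 2 repeat-rich contigs took 7.07% of its counts and 6.62% of those of Control F03, against 0.329% to 1.53% in the other libraries. On the first principal component of log2 CPM, which held 21.7% of the variance, Control M01 lay at 137. The other libraries lay between -13.7 and 7.76, so Control M01 stood apart over the tested genes as a whole. Coordinates are those of the mJacJac1 assembly, and levels are CPM from TMM-scaled totals, as mean ± SD.

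The first comparison asked which transcripts differed after 11 days of water restriction. Avp, the vasopressin precursor (ENSJJAG00000024270, chromosome 8, 82219571 to 82221324, minus strand), rose from 934 ± 597 CPM (n = 10) in Control to 3293 ± 1198 CPM (n = 10) in Dehydrated, a log2 fold change of 1.81 with an SE of 0.37. Pdyn, which encodes the prodynorphin opioid precursor stored with vasopressin (chromosome 8, 80690097 to 80717661), rose from 64.4 ± 15.2 to 142 ± 51.6 CPM, and Pcsk1, the prohormone convertase (chromosome 14, 68501495 to 68546833), from 125 ± 37 to 329 ± 131 CPM. Oxt, the oxytocin precursor (chromosome 8, 82190535 to 82191331), was at 876 ± 522 CPM in Control and 841 ± 330 CPM in Dehydrated, a log2 difference of -0.07 with an SE of 0.35 and an adjusted p of 0.972. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 20 genes rose and 2 fell. The adjusted p was 0.0388 for Avp and 0.00369 for Pdyn and Pcsk1, and the level lay above the Control median in 10, 10 and 9 of the 10 Dehydrated libraries.

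The largest rise on the log2 scale among the genes with an adjusted p under 0.05 was that of Areg, the epidermal growth factor receptor ligand amphiregulin (chromosome 11, 2177924 to 2186284), by 3.12 with an SE of 0.50. It went from 1.46 ± 1.28 to 12.0 ± 9.15 CPM. Spp1, which encodes the secreted phosphoprotein osteopontin (chromosome 2, 110555504 to 110562860), rose from 176 ± 44.7 to 564 ± 294 CPM (log2 fold change 1.69, SE 0.25) and had the smallest adjusted p, 0.00304. Gpnmb, a transmembrane glycoprotein, rose by 2.64 on the log2 scale, and Tmod1, which caps actin filaments, by 1.37, each with an adjusted p of 0.00369 and with 10 of 10 Dehydrated libraries above the Control median. Caprin2, an RNA-binding protein known to bind vasopressin mRNA (log2 fold change 0.98, adjusted p = 0.0109), the transcription factor Atf5 (0.82, 0.0226), the receptor Glp1r (1.17, 0.037) and Ptprn, a dense-core vesicle membrane protein (0.28, 0.037), also rose. Pkd2l1, a channel of neurons that contact the cerebrospinal fluid, fell from 12.8 ± 4.10 to 5.50 ± 2.49 CPM (log2 fold change -1.23, adjusted p = 0.0207). Another 10 genes past the threshold lay outside the rule for named genes and were chosen after their values were seen. Of these Alkal2, Serpinb2, Kl, Has3, Thbs1, Mest, Fkbp11, Mroh6 and Maml3 rose, by 0.58 (Maml3) to 2.54 (Alkal2) on the log2 scale. The hydroxysteroid dehydrogenase gene Hsd17b2 fell (log2 fold change -1.98, adjusted p = 0.0321). Levels in Control and Dehydrated were low for Hsd17b2 (0.943 and 0.227 CPM), Alkal2 (0.463 and 2.73 CPM) and Serpinb2 (0.546 and 2.52 CPM). These genes, Kl and Has3 had a mean under 1 log2 CPM, below the level that the simulated recovery covers. Vip, the vasoactive intestinal peptide precursor, was at 33.4 ± 19.2 CPM against 6.89 ± 9.33 CPM, above the Control median in 10 of 10 libraries. Its adjusted p was 0.0509 in edgeR with all libraries and 0.00209 in the authors' deposited table, whose fold changes match DESeq2 without Control M01. In edgeR it passed without Control F05 (log2 fold change 3.04), Dehydrated F07 or M02, or Rehydrated F03, M01 or M05. The other transcripts fixed in advance for this comparison did not pass: Gal (adjusted p = 0.847), Creb3l1 (0.851), Rasd1 (0.9), Nr4a1 (0.923), Atf4 (0.941), Hspa5 (0.869), Fosl1 (0.587), Fos (0.461) and Opn3 (0.669), and Slc12a1 was not in the tested set.

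**Figure D1:**
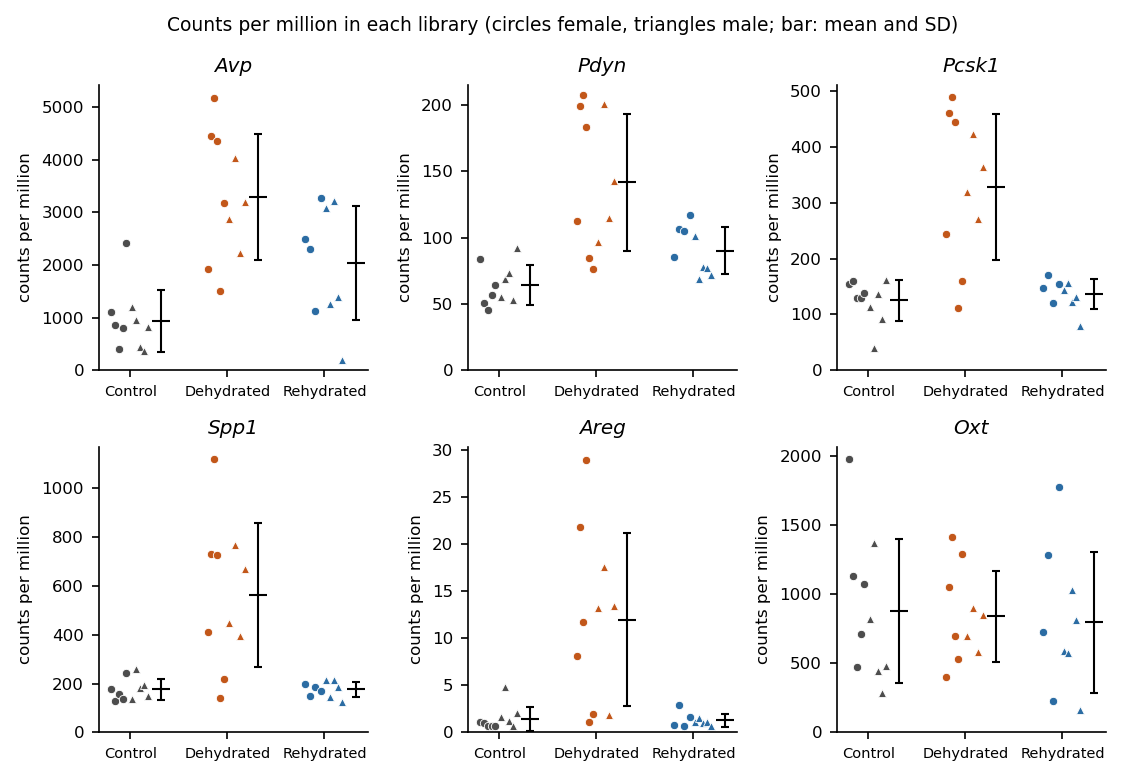
Level in CPM of 6 genes in each library (vertical axis from 0; circles female, triangles male) by group, with the mean and SD as a bar. Pcsk1 averaged 125 CPM in Control, 329 in Dehydrated and 136 in Rehydrated, while Oxt averaged 876, 841 and 797.

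In the authors' deposited table for this comparison, 46 genes had an adjusted p under 0.05, 33 higher and 13 lower, and all 22 of the edgeR genes were among them. Its fold changes match DESeq2 without Control M01, while the edgeR fit used all libraries. Of the 22 calls, 9 held with each library left out in turn: Tmod1, Spp1, Pdyn, Areg, Pcsk1, Gpnmb, Fkbp11, Thbs1 and Caprin2. The call of Avp held in 10 of 29 such fits, with a log2 fold change between 1.71 and 2.28 and an adjusted p of at most 0.114 over these fits and the other settings. The number of genes fell to 10 without Control F01, Control M03 or Dehydrated M06, 11 without Control F05 or Dehydrated F05, 12 without Control M05 or Dehydrated M09, 13 without Control F06 or Control M04, and 14 without Control F03, Dehydrated F06 or Dehydrated M08. It was 45 with DESeq2, 11 with only the compared groups in the fit and 12 with surrogate variables.

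**Figure D2:**
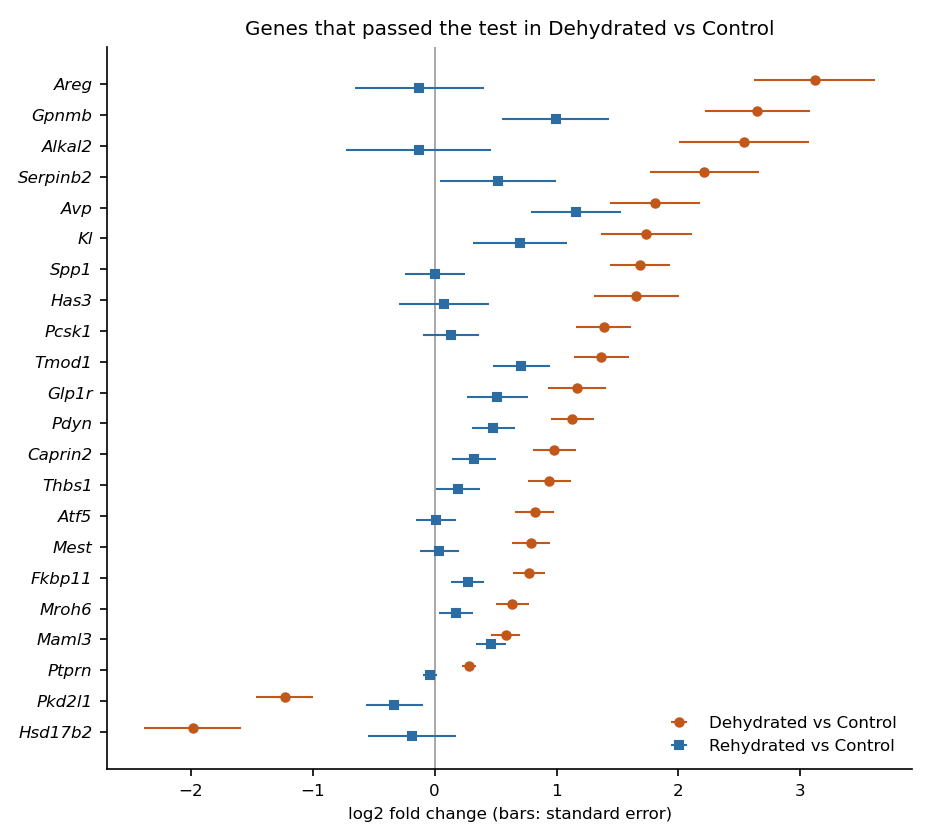
Log2 fold change (horizontal axis) with its standard error for the 22 genes past the threshold in Dehydrated against Control, shown for that comparison (circles) and for Rehydrated against Control (squares). The median size was 1.30 in Dehydrated and 0.23 in Rehydrated.

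Gene lists fixed in advance described how related transcripts moved with dehydration. Of 22 measured genes for peptide processing and dense-core granules, Pcsk1 and Ptprn rose and 20 did not pass; adjusted over the list alone, 6 rose, with Vgf, Scg2, Chgb and Pam added. The list was higher as a whole (median log2 fold change 0.12, and 0.073 without Control M01, adjusted p = 9.48e-07 by camera, and adjusted p = 0.0104 with an estimated correlation). Of 28 genes reported to respond to dehydration in the rat supraoptic nucleus, a list taken from other work and not chosen on these samples, Avp, Pdyn, Pcsk1, Atf5 and Caprin2 rose and 23 did not pass; adjusted over the list alone, 10 rose, and Fos and Adm fell. The list was higher (median 0.09, adjusted p = 1.11e-07, and adjusted p = 0.0245 with an estimated correlation). Of 18 magnocellular peptide precursors Avp and Pdyn rose and 16 did not pass; adjusted over the list alone, 5 rose (with Vgf, Cartpt and Vip) and Adm, the adrenomedullin precursor, fell. That list was higher (adjusted p = 0.00978, and adjusted p = 0.288 with an estimated correlation), but its median was -0.03 and its mean 0.33, with 9 members on each side of 0. Its adjusted p over the left-out libraries ran from 0.000754 without Control M01, where the median was 0.098 and the mean 0.37, to 0.0639 without Control F03.

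Immediate-early and activity-regulated genes, which respond to neuronal firing, were lower as a list in Dehydrated (30 measured, median log2 fold change -0.26, adjusted p = 5.98e-07 by camera, and adjusted p = 0.182 with an estimated correlation). None of the 30 passed over all genes tested; Fos was at 15.9 ± 3.46 CPM against 38.1 ± 23 CPM (adjusted p = 0.461). Adjusted over the list alone, 7 fell (Klf2, Arc, Egr4, Fos, Egr3, Fosb and Junb) and Fosl1 rose. The letter in the library name is not the sex label in 3 libraries. The list was higher in M-named than in F-named libraries in Control (M at least 3.46, F at most 3.09) and in Rehydrated (M at least 3.11, F at most 3.06), while in Dehydrated the letters overlapped. Over all libraries its mean log2 CPM was 3.04 ± 0.16 (n = 10) in Dehydrated and 3.32 ± 0.33 (n = 10) in Control, a difference of -0.28. Among libraries with an F in their name it was 3.06 ± 0.15 (n = 5) against 3.02 ± 0.10 (n = 5), a difference of 0.05 (exact permutation test, two-sided, p = 0.579). Among those with an M it was 3.01 ± 0.19 (n = 5) against 3.61 ± 0.12 (n = 5), a difference of -0.61 (exact permutation test, two-sided, p = 0.00794, the smallest that 252 permutations can give). The list's difference therefore did not hold within the libraries with an F in their name. Its call held with each library left out in turn, with an adjusted p of at most 7.98e-05.

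**Figure D3:**
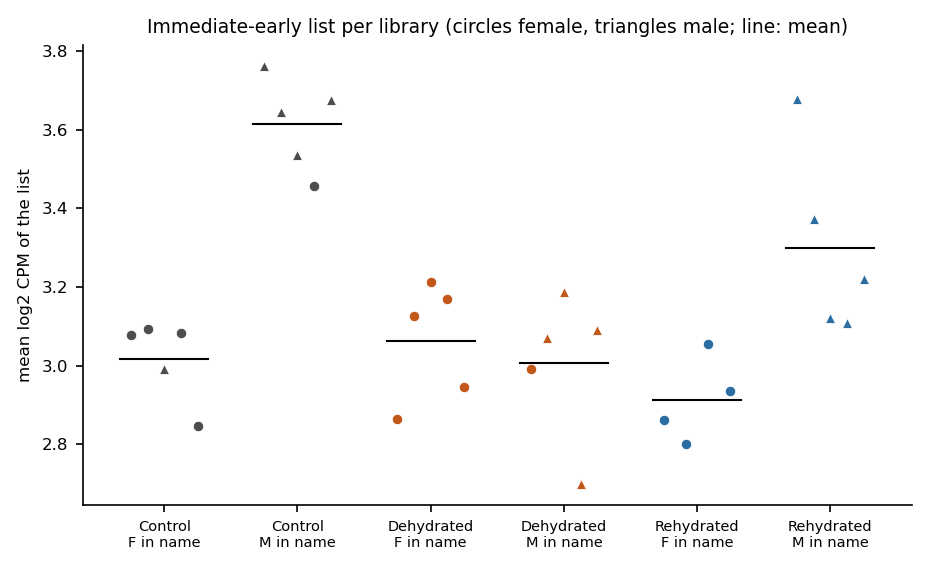
Mean log2 CPM of the immediate-early list (vertical axis) in each library by group and by the letter in the library name, with circles for females, triangles for males and a line at the mean. The means were 3.02 and 3.61 in Control, 3.06 and 3.01 in Dehydrated, and 2.91 and 3.30 in Rehydrated for F and M.

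Genes of housekeeping pathways were lower in Dehydrated as lists, with no member past the threshold over all genes. Cytosolic ribosomal proteins (70 of 74 lower, median -0.15, adjusted p = 7.1e-09), oxidative phosphorylation (50 of 55, -0.12, 9.31e-08), the proteasome (27 of 31, -0.09, 0.00031), cytosolic heat shock chaperones (16 of 21, -0.10, 0.00411) and cholesterol synthesis (17 of 22, -0.07, 0.0137) each had an adjusted p = 0.523 with an estimated correlation. Adjusted over the list alone, 1 of these genes, the chaperone Dnajb1, fell. Interferon-stimulated genes were also lower (16 of 16, median -0.82, adjusted p = 9.48e-07, and adjusted p = 0.477 with an estimated correlation), with Isg15 at 6.41 ± 1.98 CPM against 27 ± 52.9 CPM and 8 members that fell adjusted over the list alone. The log2 difference of Isg15 was -1.67 with all libraries and -0.66 without Control M01. Lists of neuronal membrane proteins were higher with no member past the threshold, either over all genes or adjusted over the list alone. These were ion and chloride transport (26 of 32 higher, median 0.10, adjusted p = 0.00225), GABA and glutamate receptors (25 of 35, 0.09, 0.0031), potassium and calcium channels (27 of 36, 0.08, 0.00978) and receptors for hormones and peptides that regulate water balance (20 of 31, 0.10, 0.0231), with an adjusted p = 0.523, 0.523, 0.544 and 0.523 with an estimated correlation.

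Control M01, which stood apart on the first principal component, also did so in some of these lists. Its mean log2 CPM was 7.21 for ribosomal proteins against 6.03 to 6.54 in the other Control libraries, and 6.90 for oxidative phosphorylation against 6.09 to 6.40. Without it the adjusted p was 0.0529 for ribosomal proteins, 0.29 for the proteasome, 0.134 for ion transport, 0.348 for channels, 0.177 for GABA and glutamate receptors and 0.356 for hormone receptors, the highest over the left-out libraries for each of these. Their lowest such values were 8.38e-13, 5.57e-06, 0.000353, 0.00201, 0.000517 and 0.0063. Oxidative phosphorylation (adjusted p = 0.0106, median -0.05) and interferon-stimulated genes (0.00257, median -0.25) kept their call without it. So did heat shock (0.0321, median -0.055) and cholesterol synthesis (0.0211, median -0.042), while the ribosomal median was -0.037 and that of the proteasome -0.020. Medians of the higher lists without it were 0.0081 for ion transport, 0.020 for channels, 0.027 for GABA and glutamate receptors and 0.040 for hormone receptors. The hormone receptor list also lost its call without Control M05 (0.0776) or Dehydrated M06 (0.0574), heat shock without Control M04 (0.072), Control M05 (0.055) or Dehydrated M08 (0.0942), and cholesterol synthesis without Control F03 (0.0614) or Control M05 (0.115). With Control M01 left out, a choice made after seeing the data, 17 genes passed in this comparison, 15 higher and 2 lower, and 14 lists against 17 with all libraries, 11 of them shared.

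Markers of other cell types were measured beside these groups. Oligodendrocyte markers were lower in Dehydrated (14 of 15, median -0.24, adjusted p = 0.0012, and adjusted p = 0.523 with an estimated correlation), with 0 members past the gene test and Mag at 349 ± 70.1 CPM against 457 ± 138 CPM; their call held with each library left out in turn. Endothelial markers were lower (12 of 15, median -0.06, adjusted p = 0.039, and adjusted p = 0.523 with an estimated correlation). That call was lost without Control F01 (0.0869), F02 (0.105), F03 (0.184) or M06 (0.0706), or without Dehydrated F03 (0.158), M06 (0.0908) or M09 (0.0692). Of 12 magnocellular neuron markers Avp and Caprin2 rose and 10 did not pass; the list was higher by its mean of 0.23 (adjusted p = 0.0224, and adjusted p = 0.471 with an estimated correlation), while its median was -0.04, and 0.018 without Control M01. It lost its call without Control F02 (0.0757) or Control M04 (0.0737). All 4 measured blood markers were lower (median -1.10), too few for a list test; adjusted over the list alone Alas2 and Hba1 fell. Astrocyte (adjusted p = 0.814), microglia (0.458), oligodendrocyte precursor (0.0701), mural (0.246), ependymal (0.527), neighbouring neuron (0.991) and forebrain markers (0.726) did not pass as lists. Without Control M01 oligodendrocyte precursor markers were lower (adjusted p = 0.00172, median -0.16).

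Other lists that did not pass in Dehydrated against Control were the unfolded protein response (adjusted p = 0.471), secretory transport (0.332), the ATF4 response (0.0897, with Atf5 past the gene test), NFAT5 targets (0.722), glucocorticoid-responsive genes (0.722), the circadian clock (0.204), glycolysis (0.742) and extracellular matrix (0.139, with Spp1 and Has3 past the gene test). Without Control M01 secretory transport (adjusted p = 0.0211) and the ATF4 response (0.0122) passed, both higher. Adjusted over the list alone, the glucocorticoid-responsive genes Fkbp5 and Hif3a rose and Gjb6 and Ddit4 fell. Signs of median, mean and test differed in the glucocorticoid list (median -0.14, mean 0.01, test down), matrix (median -0.0037, mean 0.13, test up), NFAT5 targets (median -0.06, mean -0.04, test up), astrocyte markers (median -0.01, mean 0.01, test up) and neighbouring neurons (median 0.01, mean 0.04, test down).

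**Figure D4:**
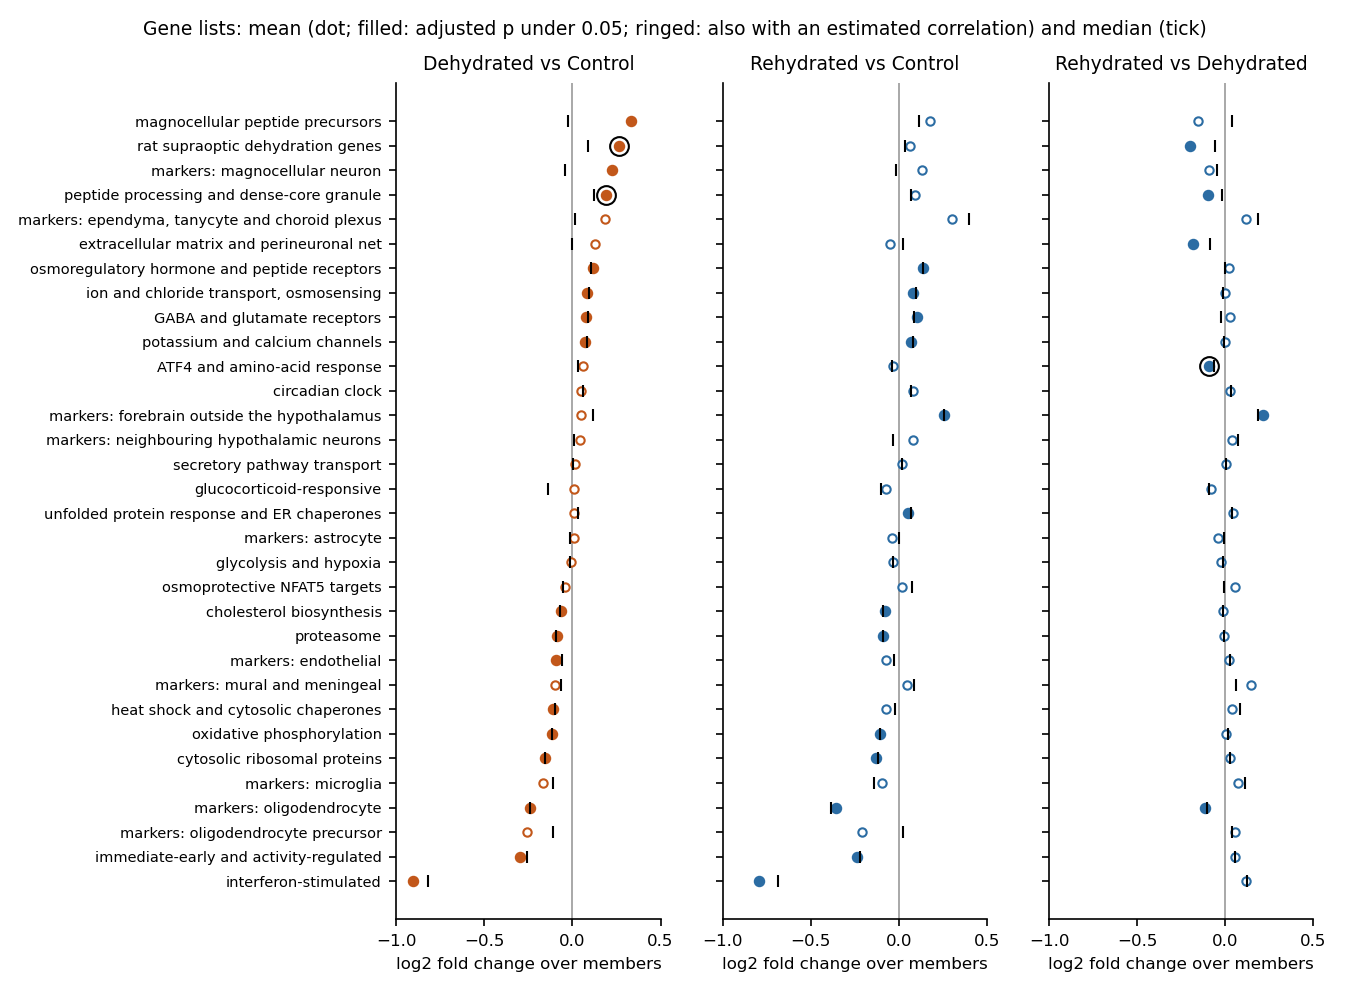
Mean (dot) and median (tick) log2 fold change over the members of each gene list, on the horizontal axis, in the 3 comparisons; filled dots have an adjusted p under 0.05, and ringed dots also with an estimated correlation. Peptide processing and rat supraoptic dehydration genes are ringed in Dehydrated against Control, at means of 0.19 and 0.26.

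The next comparison asked what differed from Control after 3 days of regained water. Avp was at 2037 ± 1086 CPM in Rehydrated (n = 9) against 934 ± 597 CPM in Control (n = 10), a log2 difference of 1.16 with an SE of 0.37, and lay above the Control median in 8 of 9 libraries; its adjusted p was 0.553. Pdyn was at 90.2 ± 17.6 CPM (log2 difference 0.48, adjusted p = 0.576, above the Control median in 9 of 9 libraries), Caprin2 differed by 0.32 (adjusted p = 0.699) and Oxt, at 797 ± 510 CPM, by -0.11 (adjusted p = 0.953). By edgeR 0 genes passed, with 1313 at an unadjusted p under 0.05 and a smallest adjusted p of 0.37, while DESeq2 called 20 genes, 3 higher and 17 lower, and 3 genes without Control M01. Without Rehydrated M05 edgeR called 2 genes, both lower. The genes with the smallest p were Col9a3, a collagen chain (9.90 ± 3.86 against 22 ± 8.83 CPM, log2 difference -1.16), the histone gene H2ax (-0.53), the kinase gene Matk (-0.32), Mkks (0.36) and Ppp1r14c (-0.39), each at an adjusted p of 0.37. The authors' deposited table for this comparison, whose fold changes match DESeq2 without Control M01, holds 4 genes with an adjusted p under 0.05. None of these 4 passed the threshold in edgeR with all libraries. They are Mkks (log2 fold change 0.38), Col9a3 (-1.22), Kank1 (-0.36) and Tnfaip6 (-1.46), of which Kank1 and Tnfaip6 lie outside the rule and were chosen after their values were seen.

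As lists, oligodendrocyte markers were lower in Rehydrated than in Control (14 of 15, median -0.39, adjusted p = 1.35e-07), as were immediate-early genes (24 of 30, median -0.22, adjusted p = 0.000155), and genes of the unfolded protein response, the folding machinery of the endoplasmic reticulum, were higher (25 of 36, median 0.07, adjusted p = 0.0171). All 3 calls held with each library left out in turn, with an adjusted p of at most 0.000313, 0.00458 and 0.0488. The immediate-early median was -0.13 without Control M01. No member of these lists passed over all genes. Adjusted over the list alone Klf2 fell; Hyou1 and Dnajc3, both chaperones, differed by 0.19 and 0.18 with an adjusted p of 0.581. For the immediate-early list the difference was -0.19 over all libraries, -0.10 among those with an F in their name (exact permutation test, two-sided, p = 0.159) and -0.31 among those with an M (exact permutation test, two-sided, p = 0.0476). Every list that passed in this comparison had an adjusted p = 0.573 with an estimated correlation. Peptide processing (0.0584), rat supraoptic dehydration genes (0.262) and magnocellular precursors (0.237) did not pass. Without Control M01 magnocellular precursors (adjusted p = 0.0447, median 0.20), secretory transport (0.0131) and microglia markers (0.0106) passed as higher. Matrix (0.0184) and oligodendrocyte precursors (0.0106) then passed as lower.

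Other lists also differed in Rehydrated from Control, most of them not without Control M01. Ribosomal proteins (median -0.12, adjusted p = 1.33e-06), oxidative phosphorylation (-0.11, 6.25e-07), the proteasome (-0.09, 0.000103), interferon-stimulated genes (-0.69, 0.000475) and cholesterol synthesis (-0.09, 0.0076) were lower. Ion transport (0.09, 0.0079), channels (0.08, 0.0386), GABA and glutamate receptors (0.09, 0.0164), hormone receptors (0.14, 0.0354) and forebrain markers (0.26, 0.0254) were higher. Adjusted over the list alone, Irf7 and Psmb8 of the interferon list fell and no member of the others passed. Without Control M01 the adjusted p was 0.179 for oxidative phosphorylation, 0.357 for the proteasome, 0.503 for interferon-stimulated genes, 0.699 for ion transport, 0.982 for channels, 0.803 for GABA and glutamate receptors, 0.579 for hormone receptors and 0.0642 for forebrain markers, and the ribosomal list turned upward at 0.803. Only the medians of forebrain markers (0.19), interferon-stimulated genes (-0.086) and cholesterol synthesis (-0.068) were then beyond 0.05 in size. Cholesterol synthesis kept its call without Control M01 (0.0131, median -0.07) and lost it without Control M05 (0.0538) or Rehydrated M04 (0.0687). Without Control M05, 8 lists passed in place of 13, and channels (0.115), GABA and glutamate receptors (0.0538), hormone receptors (0.107) and forebrain markers (0.0538) did not. Channels also lost their call without Rehydrated F03 (0.0695), M01 (0.0594), M04 (0.109) or M08 (0.146), GABA and glutamate receptors without Rehydrated M08 (0.0652), and hormone receptors without Rehydrated F04 (0.0561) or M01 (0.051). Forebrain markers lost theirs without Control M06 (0.072), Rehydrated F05 (0.125) or Rehydrated M08 (0.165). Without Control M01, 9 lists passed and 0 genes (1399 at an unadjusted p under 0.05), and 4 of the lists were shared. Signs of median, mean and test differed among lists that did not pass: matrix (median 0.02, mean -0.05, test down), oligodendrocyte precursors (0.03, -0.21, down), magnocellular markers (-0.02, 0.13, up), neighbouring neurons (-0.03, 0.08, down), microglia (-0.14, -0.10, up) and mural markers (0.09, 0.05, down).

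The direct comparison of both treated groups set 7 days of restriction and 3 of water (n = 9) against 11 days of restriction (n = 10), so it is not a before and after of 1 exposure. Spp1 fell from 564 ± 294 to 176 ± 31.8 CPM (log2 fold change -1.69, SE 0.26, adjusted p = 0.0052 in edgeR's test), Areg from 12.0 ± 9.15 to 1.28 ± 0.705 CPM (-3.24, SE 0.51, 0.0052), Pcsk1 from 329 ± 131 to 136 ± 27.2 CPM (-1.26, SE 0.23, 0.0411) and Ptprn from 830 ± 83.0 to 662 ± 50.1 CPM (-0.32, SE 0.06, 0.0411). Each lay below the Dehydrated median in 9 of 9 Rehydrated libraries. These were the 4 genes past the threshold in edgeR, all lower, against 16 with DESeq2. Avp differed by -0.65 with an SE of 0.37 and Pdyn by -0.65, with an adjusted p of 1 and 0.7. Oxt differed by -0.04 (adjusted p = 1), Vgf by -0.73 (0.302) and Atf5 by -0.81 (0.093). With only the compared groups in the fit 1 gene passed, which was higher and none of these 4. The count was 2 without Control F01, F03, F05, M03 or M05, Dehydrated F04, F05, F06, M05, M06 or M09, or Rehydrated F03, F04, F06, M01, M04, M05 or M06, 7 without Dehydrated M02 and 9 without Dehydrated F07. Spp1 and Areg kept their call with each library left out in turn, while Pcsk1 and Ptprn each lost it in 21 of the 29 fits.

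Of the lists, peptide processing (14 of 22 lower, Pcsk1 and Ptprn fell, adjusted p = 0.00612) and rat supraoptic dehydration genes (18 of 28 lower, Pcsk1 fell, adjusted p = 7.88e-06) were lower in Rehydrated than in Dehydrated, with an adjusted p = 0.118 and 0.0532 with an estimated correlation. Adjusted over the list alone, Vgf joined the first, and 6 members of the second fell (Vgf, Pdyn, Cartpt, Pcsk1, Atf5 and Caprin2). The ATF4 and amino-acid response was lower (29 of 36, median -0.07, adjusted p = 0.000725, and adjusted p = 0.0349 with an estimated correlation); its member Atf5 fell adjusted over the list alone. Extracellular matrix was lower (15 of 23, Spp1 fell and Has3 too adjusted over the list alone, adjusted p = 0.00615, and adjusted p = 0.588 with an estimated correlation), a call lost without Rehydrated F05 (0.099) or F06 (0.0593). Magnocellular precursors did not pass (adjusted p = 0.239), with a median of 0.04, a mean of -0.16 and a test that pointed down. Signs also differed for GABA and glutamate receptors (median -0.02, mean 0.03, test down), NFAT5 targets (-0.01, 0.06, up), hormone receptors (-0.0026, 0.02, up) and neighbouring neurons (0.07, 0.04, down), with adjusted p-values of 0.841, 0.868, 0.977 and 0.885. Without Control M01 the unfolded protein response and ribosomal proteins passed as higher, both at an adjusted p of 0.0469. All 4 blood markers were higher (median 1.58), and all 4 rose adjusted over the list alone, with Hba1 at 309 ± 292 against 81.5 ± 57.2 CPM. Rehydrated M04 stood apart in these markers, at a mean log2 CPM of 5.99 against 1.12 to 3.33 in the other Rehydrated libraries.

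Oligodendrocyte markers were lower in Rehydrated than in Dehydrated (13 of 15, adjusted p = 0.0248, and adjusted p = 0.979 with an estimated correlation), and forebrain markers higher (14 of 16, adjusted p = 0.0399, and adjusted p = 0.588 with an estimated correlation). The oligodendrocyte call was lost without Dehydrated F04 (0.356), F06 (0.0798) or M05 (0.0572), or Rehydrated F05 (0.944), F06 (0.108), M04 (0.0887) or M08 (0.159). The forebrain call was lost without Control F02 (0.0549), Dehydrated F04 (0.278), M05 (0.0572) or M06 (0.0614), or Rehydrated F05 (0.347), M04 (0.0676) or M08 (0.377). Both lists varied between Rehydrated libraries, with oligodendrocyte markers at a mean log2 CPM of 5.90 ± 0.64 in Rehydrated, 6.05 ± 0.34 in Dehydrated and 6.31 ± 0.36 in Control.

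Whether the dehydration genes returned was read from all 3 comparisons. Spp1, Areg, Pcsk1 and Ptprn met the rule for a return, past the threshold against Dehydrated in the opposite direction and not against Control. This is 4 of 22 genes, 18.2% with a 95% Clopper-Pearson interval from 5.19% to 40.3%, which covers counting error only. With each library left out in turn the share ran from 8.33% without Rehydrated M05 to 33.3% without Dehydrated F07. It also moved by over 1.5 times without Rehydrated F03, F06, M01, M04 or M06, or Dehydrated M02 or M08, and was 31.1% with DESeq2, 46.7% with the replicate block and 2 of 7 genes at a threshold of 0.01. The other 18 genes, Avp and Pdyn among them, were undetermined by the tests, and none met the rule for a partial return or for persistence. Rehydrated lay between Control and Dehydrated for 19 of the 22 genes, and the median ratio of the Rehydrated to the Dehydrated log2 fold change was 0.251. Both comparisons share the Control libraries. In 20 simulations of unchanged groups against those libraries the mean ratio was 0.489 and 20.9 of 22 genes had the same sign, against 19 observed. The genes were also chosen with the Dehydrated libraries that the return is read against. In the same simulations 21.2 of 22 genes moved the opposite way in Rehydrated against Dehydrated, against 22 observed. The direction alone is therefore no evidence of a return. Libraries apart from the choice gave no reading, since 0 genes were chosen in part of the animals. Over all genes the fold changes had r = 0.651, a correlation across genes, which are not independent replicates, with 0.482 simulated, and a covariance of 0.0416 with 0.0193 simulated. With the Control libraries split in 2 the r was 0.215 and 0.162, the covariance 0.0188 and 0.0152, the ratio 0.25 and 0.239, and 16 and 20 of the 22 genes had the same sign.

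Sex differences were tested over all groups, with 14 males and 15 females. Xist, the transcript that silences an X chromosome, was at 79.3 ± 12.0 CPM in females and 4.58 ± 1.33 CPM in males (log2 fold change -4.10, adjusted p = 4e-21), with no overlap between 63.7 to 104 and 2.28 to 7.03 CPM by the sex labels. These include 3 libraries whose name carries the other letter. Kdm6a, an X-linked histone demethylase that escapes silencing, was lower in males (27.3 ± 3.23 against 42.3 ± 4.14 CPM, adjusted p = 1.27e-07). Of the unnamed genes 2 moved in opposite directions, ENSJJAG00000026721 at 18.9 ± 2.45 CPM in males against 0.162 ± 0.375 and ENSJJAG00000013578 at 1.74 against 21.5 CPM. In all, edgeR called 6 genes, 2 higher and 4 lower in males. The others were ENSJJAG00000025925, at 1.01 ± 0.641 CPM in males and 0 in females, and Ccnq, lower in males and chosen after its values were seen. DESeq2 called 20. Ddx3x and Kdm5c, also X-linked, did not pass (both 0.993). The interaction test found 0 genes by edgeR whose response to dehydration differed between the sexes (1063 at an unadjusted p under 0.05, 3 with DESeq2, 4 without the libraries whose sex label was corrected) and 0 for rehydration (1085, and 0 with DESeq2). Avp differed by 1.62 with an SE of 0.48 in females and 2.04 with an SE of 0.55 in males on the log2 scale, and Pdyn by 1.26 and 1.02. Within either sex alone 0 genes passed by edgeR in Dehydrated against Control.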

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

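The tests of the immediate-early pattern and of a change in cell makeup, and the reading of the suprachiasmatic markers by their level, were chosen after the result was seen, while the test of their median and the splits of the libraries were set beforehand.

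Within groups, 132 sets of library values were searched for a library far from the rest, and 18 had a gap to the nearest library above Dixon's 95% critical value. Chance gives about 1 in 20 groups (5%) where values are independent and normally distributed. Gene levels entered as CPM without a log scale, and the sets share libraries, so the 18 cannot be weighed against that rate. The libraries with such a gap numbered 12, and 6 of the 18 gaps were in Control M01. The gap is given below as a share of its group's range. Control M01 was high in ribosomal protein genes (mean log2 CPM 7.21, others 6.03 to 6.54, gap 0.565), oxidative phosphorylation (6.90, others 6.09 to 6.40, gap 0.626), Areg (4.85 CPM, others 0.662 to 2.03, gap 0.675), Atf4 (302.1 CPM, others 138 to 220, gap 0.503), Creb3l1 (31.2 CPM, others 18.3 to 25.0, gap 0.479) and Nr4a1 (42.8 CPM, others 7.75 to 16.2, gap 0.760).

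Among the other Control libraries, F03 had a low TMM scaling factor (0.925, others 0.974 to 1.02, gap 0.513), F02 was high in Alkal2 (1.38 CPM, others 0 to 0.696, gap 0.494), M05 in Avp (2423 CPM, others 359 to 1202, gap 0.592), M03 in Rasd1 (20.3 CPM, others 8.82 to 14.8, gap 0.476) and F05 in Vip (30.3 CPM, others 0.401 to 15.1, gap 0.510). Dehydrated M02 was high in ribosomal protein genes (6.50, others 6.13 to 6.28, gap 0.589). In Rehydrated, M04 was high in blood markers (mean log2 CPM 5.99, others 1.12 to 3.33, gap 0.546), F04 in Areg (2.92 CPM, others 0.711 to 1.68, gap 0.563), M08 in Glp1r (14.9 CPM, others 5.50 to 9.87, gap 0.533) and F05 in Kl (3.73 CPM, others 1.19 to 1.86, gap 0.737). Rehydrated M01 was high in Fos (65.2 CPM, others 11.1 to 31.8, gap 0.618) and in Nr4a1 (40.9 CPM, others 6.48 to 12.4, gap 0.827).

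The immediate-early list was lower in Dehydrated than in Control. Within Control, sex of the animals is argued against, because the lowest library with an M in its name lay 0.36 log2 CPM above the highest with an F, while Control M05 is female and Control F03 male by their labels. A fall of the same size in all dehydrated animals was tested as well. Among libraries with an F in their name the difference was 0.046. An exact permutation test of it against the all-library difference of -0.28 gave p = 0.00794, the smallest that 252 permutations can give. The test cannot decide this, because the F-named difference was seen before the test was chosen. It also took -0.28 as exact, although the same F-named libraries enter that value. Whether the Control libraries with an M in their name were handled apart from the rest stays open: the F-named difference prompted the idea and does not support it, and in Rehydrated, where letter and sex coincide, the M-named libraries also lay above the F-named ones (means 3.30 and 2.91, exact permutation test, two-sided, p = 0.0238). A response to water restriction in the M-named animals alone stays open too, since the labels do not say what the name letter stands for beyond sex. The sample numbers in the count headers run through the M-named libraries first and the F-named ones next, with Rehydrated M04 numbered last. Within each letter the numbers run through Control, Dehydrated and Rehydrated in turn. That library aside, neither the letter nor, within a letter, the group can be told apart from sample order. This holds for every treatment comparison, and what the order stands for is not given.

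Among genes with an adjusted p under 0.05, 20 rose in Dehydrated, with a median log2 fold change of 1.27, and Spp1 and Gpnmb rose by at least 1.69. A larger share of magnocellular neurons in the Dehydrated punches could raise Avp, Pdyn and Caprin2. The magnocellular marker list had a median of -0.040 (0.018 without Control M01) with an SD of 0.59 over its members. This argues against an even rise of its markers by as much as the median risen gene. The list was higher by its mean of 0.23 (adjusted p = 0.0224 by camera, and adjusted p = 0.471 with an estimated correlation). Markers that other cells express too would hide a larger share of these neurons, which therefore stays open. An even rise of all microglia, which express Spp1 and Gpnmb, is argued against by the microglia list. Its median was -0.11 (0.043 without Control M01) with an SD of 0.30, and both medians lie below the rise of 1.69 by more than that SD. The list's marker Csf1r was at 64.3 CPM in Dehydrated against 66.3 CPM in Control. Gpnmb was at 1.83 CPM in Control, so a small group of microglia rich in it could go unseen in the list and stays open. A response of the cells to water restriction stays open as a hypothesis, untested apart from the group difference itself.

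Vip was at 33.4 CPM in Dehydrated and 6.89 CPM in Control. Its adjusted p was 0.0509 in edgeR, 0.000925 with DESeq2 and 0.00209 in the authors' table, whose fold changes match DESeq2 without Control M01. In edgeR it passed in 6 of 29 fits with a library left out. Punches that took in suprachiasmatic tissue, a nearby source of Vip, could give such a difference. Of 9 other suprachiasmatic markers 7 were in the tested set, 3 were higher and 0 passed, and their median log2 fold change was -0.031 with an SD of 0.27 against 2.56 for Vip. This does not exclude that source, although the bound set beforehand was met: the markers' median level in Control, 17.8 CPM, lies above that of Vip, and Nms and Six6 are low, at 2.45 and 1.42 CPM, so a small share of tissue rich in Vip would go unseen. Such tissue and a response of Vip to water restriction stay open, as does chance by the edgeR test alone.

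The libraries were split 100 times into groups of the same sizes, the real split included. Of these splits 1 gave as many genes as Dehydrated against Control (22, highest other 0). For the sex comparison 1 did so too (6, highest other 0). This argues against chance for both counts, with 1 in 100 the smallest share possible here. Xist already separates the sex labels without overlap, so the splits add little for sex. Single genes are not covered: 9 of the 22 dehydration calls held with each library left out in turn. For Rehydrated against Dehydrated 2 of 100 splits, the real one included, gave at least 4 genes, a share under 0.05. The other of these gave 12 genes, more than the real one, and what sets its libraries apart was not tested. The evidence against chance is therefore weak here. For Rehydrated against Control and for the interaction with sex in dehydration and rehydration the real count was 0, which any split reaches, so the splits say nothing about chance. Their highest other counts were 1, 4 and 21 genes. Chance cannot be excluded for the lists: 17 in Dehydrated against Control (9 splits as high, highest other 19), 13 in Rehydrated against Control (35 splits, highest other 18) and 6 in Rehydrated against Dehydrated (52 splits, highest other 16).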

How the results depend on the processing

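The alternatives that left out Control M01 with Rehydrated M04, with Control F03 or under DESeq2, took the name letter as covariate or removed repeat-contig genes were chosen after the result was seen; the others were set beforehand. Of 8875 values of named genes over all settings 8448 kept direction and side of the threshold, 315 lost the call, 33 gained it and 79 changed sign, all for genes without a call in the comparison. Of 1440 values of the lists that passed with all libraries 1257 kept both, 171 lost the call and 12 changed direction. Lists that gained a call are not among these values. Of 327 counts and returned shares 258 were taken as unchanged. For a count this meant within 1.5 times, and for a returned share only within its interval from 5.19% to 40.3%. RLE size factors, a stricter count filter, the non-robust fit, the name letter as covariate and the removal of repeat-contig genes left all their values unchanged by this rule. These were 10, 10, 6, 7 and 7 values, since not every count was made under each setting. Tmod1, Spp1, Pdyn, Areg, Pcsk1 and Gpnmb kept their call in all 29 leave-outs and 16 other settings, which do not include the sexes alone. The cause was not tested for any change given here, except that fewer samples enter the sexes alone and the left-out fits. The simulated recovery at 1.5-fold was 46 of 67. Choosing the dehydration genes in part of the animals (11 or 9 libraries) and reading them in the rest gave no value, since 0 genes were chosen.

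With DESeq2 the counts were 45 genes in Dehydrated against Control, 20 in Rehydrated against Control, 16 in Rehydrated against Dehydrated, 20 by sex and 3 for the sex difference in dehydration; with Control M01 also left out they were 47, 3 and 20 in the treatment comparisons. With no low-count filter 16 genes differed by sex. With only the compared groups in the fit, 11 genes passed in Dehydrated against Control and 1 in Rehydrated against Dehydrated; at a threshold of 0.01, 7 and 2. Females alone gave 0 genes in Dehydrated against Control, 2 in Rehydrated against Control and 0 in Rehydrated against Dehydrated, and males alone 0 in the first and 1 in the last. Without the libraries of corrected sex 4 genes had a sex difference in dehydration. With surrogate variables 12 genes passed in Dehydrated against Control, and 9, 3 and 3 lists in the 3 comparisons. With the oligodendrocyte covariate 7 lists passed in Rehydrated against Control and 3 in Rehydrated against Dehydrated. With an estimated correlation 2, 0 and 1 lists passed by camera. Without Control M01 and Rehydrated M04, 7 lists passed in Rehydrated against Control. Without Control M01 and Control F03, 12 genes and 11 lists passed in Dehydrated against Control and 5 lists in Rehydrated against Control.

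Lists that changed direction had these adjusted p-values. With surrogate variables channels, GABA and glutamate receptors, ribosomal proteins and the proteasome were each at 0.653 in Dehydrated against Control, and channels at 0.849, GABA and glutamate receptors at 0.643 and ribosomal proteins at 0.451 in Rehydrated against Control. In that comparison ribosomal proteins were at 0.803 without Control M01, 0.0972 without it and Rehydrated M04 and 0.339 without it and Control F03. Channels were at 0.873 without Control M01 and Rehydrated M04, and GABA and glutamate receptors at 0.958 without Control M01 and Control F03. Over the left-out libraries the ribosomal list ran from 1.27e-09 (without Control F05) to 0.803.

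Genes that changed sign, none with a call, had these log2 fold changes. In Dehydrated against Control, without Control M01 and Control F03, Atf4 was at 0.045, Nr4a1 at 0.11 and Oxt at 0.17; without Control M01 and Rehydrated M04, at 0.057, 0.14 and 0.10; with DESeq2 without Control M01, at 0.056, 0.13 and 0.10; and with surrogate variables, at 0.080, 0.24 and 0.30. In Rehydrated against Control, the same settings gave Nr4a1 at 0.20, 0.28, 0.23 and 0.33 and Oxt at 0.15, 0.090, 0.074 and 0.28, and surrogate variables gave Gal at -0.097. With the oligodendrocyte covariate Oxt was at 0.058 in Dehydrated and 0.046 in Rehydrated against Control, and Gal at -0.14 in Rehydrated. Without the libraries of corrected sex Gal was at -0.061 in Rehydrated against Control and Oxt at 0.018 in Rehydrated against Dehydrated. With only the compared groups Opn3 was at -0.0018 in Rehydrated against Control. Without the sex covariate Rasd1 was at 0.0022 and without Control M01 and Rehydrated M04 Creb3l1 at -0.0057, both in Rehydrated against Dehydrated.

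With each library left out in turn, genes in Dehydrated against Control ran from 10 (without Control F01) to 27 (without Dehydrated F07), in Rehydrated against Control from 0 (without Control F01) to 2 (without Rehydrated M05) and in Rehydrated against Dehydrated from 2 (without Control F01) to 9 (without Dehydrated F07). Lists ran from 8 (without Control M05) to 18 (without Rehydrated M05) in Rehydrated against Control and from 3 (without Rehydrated F05) to 9 (without Dehydrated F03) in Rehydrated against Dehydrated. In Dehydrated against Control, Oxt ran from -0.16 (without Control M04) to 0.10 (Control F01), Nr4a1 from -0.27 (Dehydrated F04) to 0.13 (Control M01) and Atf4 from -0.074 (Control F05) to 0.057 (Control M01). In Rehydrated against Control, Oxt ran from -0.30 (Rehydrated F06) to 0.074 (Control M01), Nr4a1 from -0.56 (Rehydrated M01) to 0.23 (Control M01), Gal from -0.15 (Rehydrated M06) to 0.20 (Control M01) and Opn3 from -0.048 (Rehydrated M06) to 0.12 (Control F03). In Rehydrated against Dehydrated, Oxt ran from -0.23 (Rehydrated F06) to 0.10 (Rehydrated F05), Nr4a1 from -0.34 (Rehydrated M01) to 0.14 (Dehydrated F04), Rasd1 from -0.14 (Rehydrated F05) to 0.042 (Rehydrated F03) and Creb3l1 from -0.0093 (Rehydrated M04) to 0.082 (Rehydrated M05).

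The replicate numbers do not pair the libraries: the deviations of 19 same-numbered pairs had r from -0.115 to 0.081 across genes, 0 of them above 0.1, and 0 of 23 libraries with a partner correlated best with their own number. With the replicate block 15 genes passed in Dehydrated against Control (12 shared), 0 in Rehydrated against Control and 7 in Rehydrated against Dehydrated, and the returned share was 46.7%. Under the block these uncalled genes changed sign: in Dehydrated against Control Gal (0.035), Nr4a1 (0.34), Rasd1 (0.095), Oxt (0.35) and Atf4 (0.066), in Rehydrated against Control Nr4a1 (0.048), Opn3 (-0.050) and Oxt (0.11), and in Rehydrated against Dehydrated Creb3l1 (-0.048), Nr4a1 (-0.29) and Hspa5 (-0.018).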
